A study of Homo sapiens with 18 samples.

How the data were processed

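Human neural progenitors of the XCL1 DCXpGFP line were differentiated with or without amyloid-β 1-42, and viable cells of days 0, 7, 13 and 20 were sequenced with a droplet-based 3' kit, per the labels' protocols. Reads were processed with Cell Ranger 3.0.1 and STAR against GRCh38, per the submitters' processing notes; the version of STAR is not given in the sources used here. The authors deposited UMI counts per gene and cell as 1 pooled matrix of whole numbers from 1 to 1412 (98250043 entries above 0), with gene symbols and barcodes. Filters on cells are not given in the sources used here; every deposited cell had at most 10% of its UMIs from mitochondrial genes, and 50 genes had no UMI. The 7 chromatin accessibility libraries were not analysed here.

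The groups of the 11 RNA libraries were taken from the labels. The number after each barcode, 1 to 7, could not be tied to a library, and no condition was inferred from the values. The planned tests of amyloid-β against control, of the days and of their interaction were therefore not run. As planned for this case, the pool was described as 1 sample without a test between groups. Values of the 7 barcode sets are given as each value, or as a median and range, and no p-value was computed. The comparison of cell classes within sets was added after the data were seen.

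The deposited counts were not alike in all sets. In set 4 all 5601416 counts were even, and in sets 1 to 3 counts of 2 were in excess. Poisson intervals (exact, 95%) were therefore computed for sets 1 to 4 from counts divided by 2, and for sets 5 to 7 from the counts as deposited. All intervals cover counting error only. CPM were computed from the deposited counts as UMIs of a gene per 1000000 UMIs of the set, class or cluster.

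For clustering, counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes were chosen over sets with Scanpy 1.11.5. Genes were scaled, 30 principal components were computed with NumPy 2.4.6, and 15 nearest neighbours were found with scikit-learn 1.9.0. Leiden clustering (igraph 0.11.9) used a resolution of 0.5. No correction between sets was applied. Python 3.11.15, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used otherwise. Scrublet, as implemented in Scanpy, marked 145 cells (0.341%), and no cell was removed as a doublet. Whether the caller missed doublets or cells had been filtered before deposit was not tested. A clustering without the marked cells, and sums without the 5% of cells with the most UMIs in each set, were run as alternatives.

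The 17 marker lists and 25 gene lists were fixed before the data were examined. Of the list entries 10, and of the marker entries 12, matched no symbol of the matrix and were not used; 3 list entries were matched through an older symbol in the RefSeq gene table. A marker was raised when its CPM in the cluster was at least 2 times that in the rest of the pool and at least 10% of the cluster's cells had a UMI of it. A cluster was named for the list with the most raised markers, at least 3, unless its 10 leading genes by fold held more markers of another class than of its own. Immature and mature neuron lists count as 1 class, and markers of glutamatergic and GABAergic neurons do not go against a neuron name. These thresholds and this exception were set after a first clustering had been seen, and the thresholds were changed once. That first clustering, with another implementation at the same resolution, gave another number of clusters. By this rule clusters 9 and 10 were intermediate progenitor-like; as genes of serotonergic neurons led cluster 9, the text gives both by number. Leading genes needed 50 CPM and 100 UMIs in the cluster.

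Classes were compared within each set that had at least 50 cells of both. UMIs were summed per class and set, and log2 folds were computed from CPM with 1 added, which understates the folds of low genes. Genes with a mean of at least 5 CPM counted as measured, and a gene counted as higher or lower when it passed 1.5-fold the same way in every set. The median of a list is that of its genes' median folds over sets, and its range is that of the medians taken in each set. This median was set beside 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these sets. On counts simulated from the real levels with known changes, 85.6% of 97 genes changed 2-fold and all of 96 genes changed 4-fold were called among 10698 genes run, and none of 10505 unchanged genes was. The simulation gave each class an equal and large share of every set's UMIs, with Poisson counts and no spread between sets. Its rates therefore do not carry over to real classes with few cells.

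Genes named in the text follow a rule fixed before the data were examined: the 5 leading genes of each cluster, up to 4 members of each list by level, the 8 largest folds in each direction with at least 50 CPM and 100 UMIs on the higher side (written for libraries, and applied here to the classes of every set), and APP, APOE, MAPT, DCX, SOX2, PAX6, MKI67 and STMN2 in every set. Some genes that this rule names are not reported here. Other genes were chosen after their values were seen, which applies to BACE2, SORL1, LRP1, TUBB3, MC1R and the genes of the closing observations. To compare genes per cell, 1000 cells of each set were thinned to 1200 UMIs. Alternatives fixed before the data were examined were a resolution of 1.0, 50 principal components and only cells with at least 1000 genes. Alternatives added after the data were seen were clustering without list and marker genes, omission of the cells marked as doublets, of the cells with most UMIs, of set 4 or of sets 1 to 4, cluster 9 left unnamed, totals without mitochondrial, ribosomal protein and MALAT1 transcripts, and a pseudocount of 10 CPM.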

Results

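The series follows human neural progenitor cells of the XCL1 DCXpGFP line, which carries a green fluorescent protein reporter under the doublecortin (DCX) promoter, as they differentiate to neurons with or without amyloid-β 1-42 peptide at 50 nM. Cells were taken before differentiation (day 0) and on days 7, 13 and 20 of it, dead cells were removed by sorting on TO-PRO-3, and RNA libraries were made with a droplet kit that reads the 3' ends of transcripts. The labels describe 11 RNA libraries in 7 groups: 1 group at day 0, and an amyloid-β and a control group at each later day. The 4 groups of days 13 and 20 have 2 libraries each and the other 3 have 1; the labels do not say whether the second library is a second culture or a repeat of the first. A further 7 chromatin accessibility libraries were not analysed here.

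The expression data are 1 pooled matrix of unique molecular identifier (UMI) counts for 23350 genes in 42575 cells, with 299961387 UMIs in all. Each barcode ends in a number from 1 to 7, and these 7 barcode sets could not be tied to a library, day or treatment. The comparisons of amyloid-β with control cultures and of the days, which the design implies, were therefore not made. The pool was described as 1 sample, and values of the 7 sets stand side by side without order or test. The sets held 4026 to 13450 cells and 21923776 to 78150631 UMIs. Median UMIs per cell were 8559, 5458.5, 7701, 4200, 5543, 7553 and 9846 in sets 1 to 7, and median genes per cell were 2705, 2041, 2592.5, 1091, 2021, 2465 and 3243. In cells thinned to 1200 UMIs the medians were 763, 749.5, 719, 630, 676, 669 and 756 genes. All counts of set 4 were even, and with these divided by 2 before thinning its median was 716 genes.

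The cells formed 11 clusters, of which 7 held neural progenitor-like, cycling-like or neuron-like cells, 2 (clusters 9 and 10) had mostly intermediate progenitor markers raised and are given by number, and 2 received no name. Neuron-like cells were 36.6% of the pool (exact binomial 95% interval 36.1 to 37.1%), neural progenitor-like cells 22.3% (22.0 to 22.7%), cells of clusters 9 and 10 11.1% (10.8 to 11.4%), cycling-like cells 6.47% (6.24 to 6.71%) and unnamed cells 23.5% (23.1 to 23.9%). These intervals cover counting error only. At a Leiden resolution of 1.0 the cells formed 21 clusters and the cycling-like share was 20.9%. All 5591 cells of cluster 1, which has no name at 0.5, then lay in cycling-like clusters, as did 669 cells (15.1%) of cluster 5. Unnamed cells were 9.51% at that resolution and 14.4% with the clustering made without list and marker genes.

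Neural progenitor-like cells lay in 2 clusters with different leading genes. Cluster 2, with 4990 cells, was led by BCAN (brevican, a matrix proteoglycan), PMP2, FBLN5, CYP26B1 (which breaks down retinoic acid) and C1orf61; BCAN stood at 414 counts per 1000000 UMIs (CPM) there and 11.2 CPM in the rest of the pool. Of 15 measured progenitor markers 4 were raised in it, SOX9, SLC1A3, FABP7 and NOTCH1, and the astrocyte list had 3 raised members of 12. The 10 leading genes of cluster 2 held 1 progenitor marker, SLC1A3, and 1 astrocyte marker, S100B. Cluster 4, with 4525 cells, was led by HES5, a Notch target, at 570 against 43.5 CPM, followed by AL139246.5, SYNDIG1, SFRP2 and TACR1. Its raised markers were PAX6, HES5, SOX9, SOX3 and NOTCH1. Sets 1 and 2 held 99.6% of cluster 2, and sets 3 to 6 held 99.9% of cluster 4.

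The intermediate progenitor list had the most raised markers in clusters 9 and 10. Cluster 10, with 2350 cells, was led by CHRNA3, NEUROD4, EBF2, NHLH1 and LMO1, and 9 of 11 measured intermediate progenitor markers were raised, among them NEUROG2, INSM1 and HES6. Cluster 9, with 2355 cells, was led by GATA2, SPX, GATA3, FEV and GATA3-AS1, with INSM1, HES6, DLL1 and DLL3 among its raised markers. GATA2 stood at 429 CPM in cluster 9 and 12.2 CPM elsewhere. Its 10 leading genes held 1 intermediate progenitor marker, DLL3, 1 mature neuron marker, CALB1, and the serotonergic neuron genes GATA2, GATA3 and FEV. At a resolution of 1.0 65.1% of the cells of cluster 9 lay in neuron-like clusters and 23.9% in intermediate progenitor-like clusters, against 2.85% and 97.1% for cluster 10, so cluster 9 is compared by number and not by that name. Sets 3 to 6 held 99.3% of cluster 9, and sets 1 and 2 held 96.3% of cluster 10. Cluster 8, with 2754 cells, was cycling-like, with all 15 markers of that list raised and HIST1H1B, HIST1H2AH, ATAD2, FAM111B and HIST2H2AC leading.

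Neuron-like cells lay in 4 clusters. Cluster 3, with 4966 cells, was led by PMEL, NEFM, C1QL1, PCSK2 and SNCG, and its raised immature neuron markers were DCX, STMN2, STMN4, ELAVL3, ELAVL4, INA, MLLT11 and CRMP1. Of 11 intermediate progenitor markers 6 were also raised in it, and at a resolution of 1.0 22.2% of its cells lay in intermediate progenitor-like clusters. The neurofilament gene NEFM stood at 5103 CPM there and 540 CPM elsewhere. Cluster 6, with 4210 cells, was led by LHX5-AS1, TSHZ2, LHX5, CDH8 and RUNX1T1. Cluster 7, with 4065 cells, was led by RTN1, FEV, CRYBA2, CHD5 and SLC17A8, and 11 of 17 mature neuron markers were raised, including RBFOX3, SYT1, SNAP25 and MAPT. Cluster 11, with 2343 cells, was led by LINC01828, NR4A2, PCSK1, LRP1B and AC109466.1. Cluster 3 came almost wholly from sets 3 to 6 (99.6%), while clusters 6, 7 and 11 came from sets 1 and 2 (99.7%, 99.4% and 99.4%).

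Of the unnamed clusters, cluster 1 held 5591 cells, 99.9% of them from set 7. It was led by ADM, A2M, ADGRL4, LPL and ANXA1; all 15 cycling markers were raised in it, but none was among its 10 leading genes, where the mesenchymal marker TAGLN stood at 978 CPM against 30.9 CPM elsewhere. Cluster 5, with 4426 cells, had MAL, ID3, ID1 and TRIM48 among its leading genes, and no marker list had 3 raised members. ID1 and ID3, targets of BMP signalling, stood at 172 and 371 CPM there and at 33.7 and 61.0 CPM elsewhere.

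The share of neuron-like cells was 56.5%, 58.8%, 32.6%, 30.7%, 21.4%, 22.7% and 0.160% in sets 1 to 7. Neural progenitor-like cells made up 26.8%, 27.6%, 45.7%, 49.5%, 2.67%, 1.99% and 0.0534%, and cycling-like cells 1.90%, 1.93%, 8.37%, 8.34%, 16.5%, 17.2% and 0.0890%. Cluster 10 held 14.7% and 11.7% of sets 1 and 2 and at most 1.47% of any other set, and cluster 9 held 9.36%, 7.27%, 16.1% and 16.7% of sets 3 to 6 and at most 0.178% of any other. Unnamed cells were 43.1% of set 5, 41.4% of set 6 and 99.5% of set 7, and at most 3.89% of any other set. In set 7 they were almost all of cluster 1, where all 15 cycling markers were raised. The low cycling-like share of set 7 thus rests on the naming rule, and its progenitor-like share leaves out any progenitors in cluster 1. In sets 5 and 6 unnamed cells were almost all of cluster 5, so the progenitor-like shares there leave out any progenitors in it. The clusters largely followed the sets, and sets could not be tied to conditions, so these shares describe the pool and not a change between conditions.

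**Figure D1:**
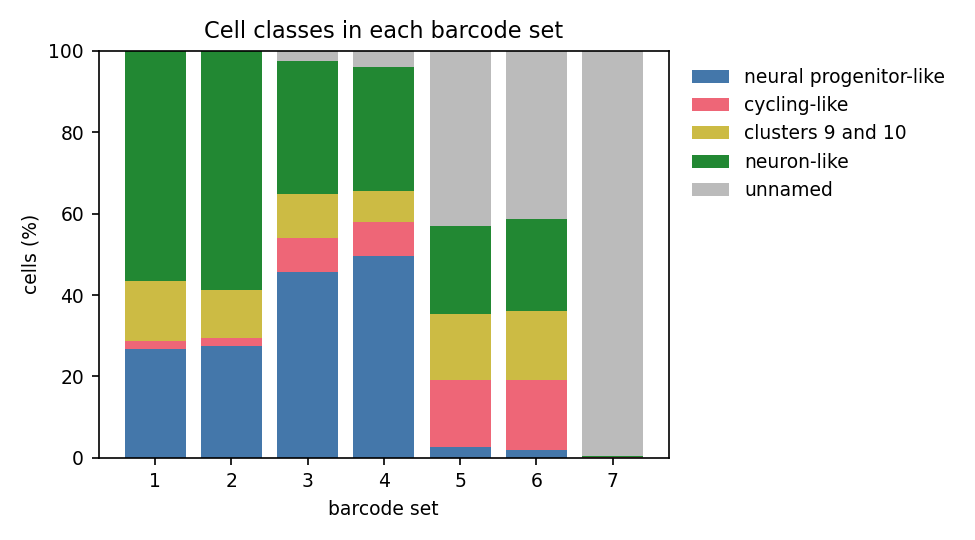
Stacked bars give the percentage of cells in each class (vertical axis) for each of the 7 barcode sets (horizontal axis). Neuron-like cells make up 58.8% of set 2 and 21.4% of set 5, and 99.5% of set 7 lies in unnamed clusters.

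The level of 8 genes was read in every set. STMN2, a microtubule regulator of growing axons, stood at 3671, 4211, 1985, 1989, 1201 and 1207 CPM in sets 1 to 6 and at 4.94 CPM (95% Poisson interval 4.38 to 5.55) in set 7. DCX, whose promoter drives the reporter, ranged from 269 to 569 CPM in sets 1 to 6 and was 4.91 CPM (4.35 to 5.51) in set 7. MAPT, which encodes tau, was 202, 234, 78.9, 80.9, 18.7, 20.8 and 1.11 CPM. MKI67, a proliferation marker, was 8.90, 9.55, 36.3, 37.7, 61.6, 63.8 and 189 CPM. PAX6 was highest in set 4 at 348 CPM and lowest in set 7 at 28.5 CPM, while SOX2 stayed between 306 and 482 CPM. APP, which encodes the amyloid precursor protein, was 525 and 527 CPM in sets 1 and 2, 285 and 279 CPM in sets 3 and 4, and 158 to 168 CPM in sets 5 to 7. APOE ranged from 17.6 to 44.2 CPM.

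**Figure D2:**
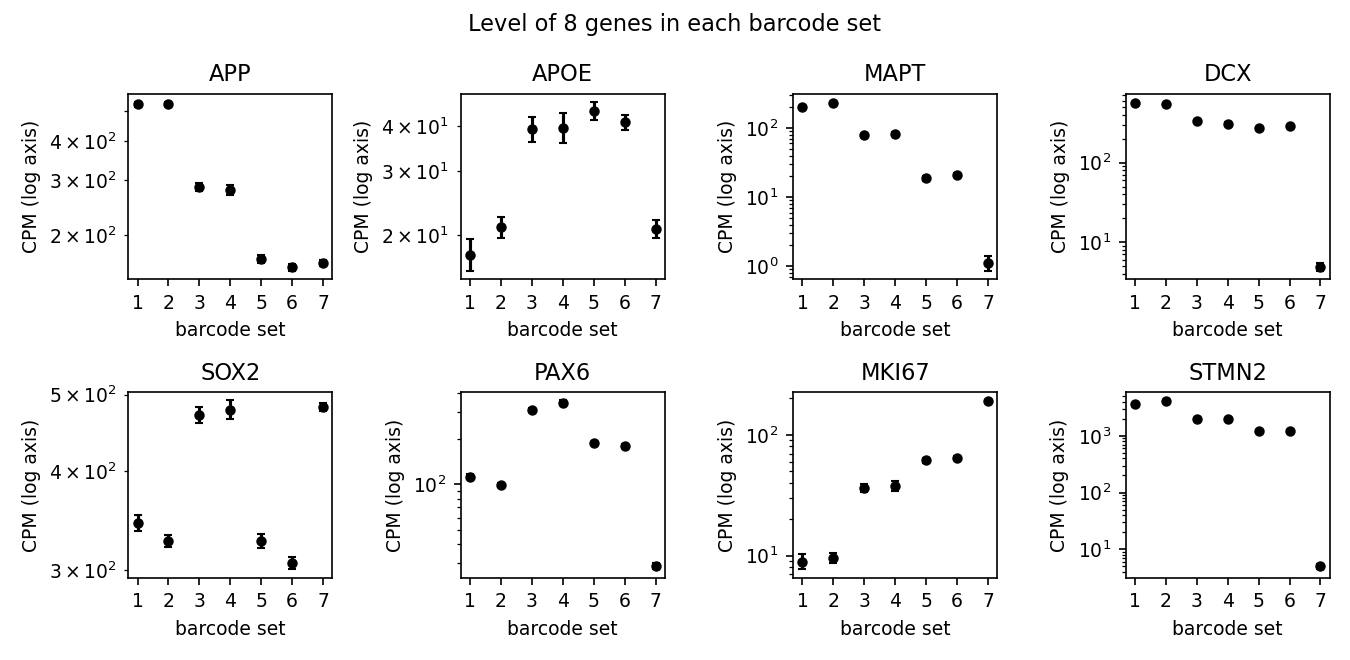
Points give the level of each of 8 genes in CPM (vertical axis, log scale) in each of the 7 barcode sets (horizontal axis), and bars give 95% Poisson intervals, with counts of sets 1 to 4 divided by 2. STMN2 lies at 1201 CPM or above in sets 1 to 6 and at 4.94 CPM in set 7.

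Classes were then compared within sets, a comparison chosen after the data were seen, in the 6 sets with at least 50 cells of each class. Of 10589 genes measured, 1214 were at least 1.5-fold higher and 753 at least 1.5-fold lower in neuron-like than in neural progenitor-like cells in each of the 6 sets. With 50 principal components 1911 were higher, and with a pseudocount of 10 CPM 770 were higher and 493 lower. The largest folds were those of NEFM (median log2 fold 6.83 over sets, from 3.38 to 7.09), THSD7A (5.87), TTC9B (5.84), SHOX2 (5.73), LHX5-AS1 (5.70), POU2F2 (5.35), MYT1L (5.26) and STMN2 (5.15). The genes lower in neuron-like cells were led by IFITM3 (-4.60, from -4.86 to -4.04), TFPI2 (-4.32), SPARC (-4.14), CTGF (-4.13), SFRP2 (-4.12), IGFBP5 (-4.11), NTRK2 (-4.00) and FBXO32 (-3.83). The clusters were drawn from the same counts, so these folds describe how the classes differ and are no independent test of it. The progenitor-like cells came from cluster 2 in sets 1 and 2 and from cluster 4 in sets 3 to 6, with only 127 and 100 cells in sets 5 and 6. In cluster 2 the astrocyte list also had 3 raised members, so sets 1 and 2 do not compare against cells with progenitor markers alone. The neuron-like cells came almost wholly from clusters 6, 7 and 11 in sets 1 and 2 and from cluster 3 in sets 3 to 6. Medians over sets thus mix unlike neuron-like clusters.

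All 19 measured genes of the presynapse list were higher in neuron-like cells in every set, with a list median of 2.51 on the log2 scale (2.08 to 2.77 over sets), at percentile 100 of 10000 random lists matched on expression. SYT1, the calcium sensor of vesicle release, stood at a median of 1155 CPM in neuron-like and 222 CPM in progenitor-like cells, and SYT4 and VAMP2 had median log2 folds of 3.93 and 1.65. In the list of axon guidance and cytoskeleton genes 18 of 29 were higher and 1 lower, with a median of 1.64; MAP1B was at 4615 against 986 CPM, STMN1 at 4175 against 1263 CPM and TUBA1A at 11744 against 4496 CPM. Of the postsynapse and receptor genes 9 of 15 were higher and none lower (median 1.52). Among the most abundant of them GRIA2 (3.58) and GRIA4 (3.21) were higher in every set, while GRIN2B (2.30) and GRIA1 (-0.60) were not called. Ion channel genes had a median of 1.12, with 6 of 11 higher and 2 lower; SCN2A (2.91) and SCN3A (1.63) were higher and SCN1A (0.39) was not called. Members such as SYT1, SYT4, STMN2 and GRIN2B are also neuron markers used for naming, so the percentile is no independent test. With the clustering made without any list or marker gene, the medians were 2.58 for presynapse, 1.63 for axon guidance and cytoskeleton, 1.62 for postsynapse and receptors and 0.84 for ion channels. Those clusters were still named by the marker lists. Over the alternatives the presynapse median ran from 1.61 to 2.58 and the postsynapse median from 0.89 to 1.75.

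Of the Notch signalling genes 7 of 11 were lower in neuron-like cells and none higher (median -2.21, percentile 0, and -3.04 to -1.06 over the alternatives). HES5 stood at a median over sets of 6.80 CPM in neuron-like and 69.7 CPM in progenitor-like cells, and HES4 had a fold of -0.92. The median of 69.7 CPM is over sets with unlike progenitor-like clusters, and HES5 stood at 570 CPM in cluster 4 as a whole. HES5 and HES4 are also neural progenitor markers used for naming, so this percentile too is no independent test. The Notch ligand genes JAG1 (-0.59) and DLL3 (1.08, at 126 against 55.1 CPM) passed in neither direction. Of the BMP and TGF-beta response genes 6 of 9 were lower and 1 higher (median -1.43), with ID3 at -3.47, ID4 at -1.42, CYR61 at -3.54 and CTGF at -4.13; the median ran from -2.42 to -1.23 over the alternatives. Extracellular matrix genes had a median of -1.54 with 8 of 13 lower, among them SPARC at 19.7 against 337 CPM, but COL4A2 (-1.37), COL6A1 (0.20) and VCAN (0.47) were not called; the median ran from -1.92 to -0.82 over the alternatives. Of the WNT genes 4 of 9 were lower (median -0.95, and -1.75 to -0.90 over the alternatives), including SFRP2 (-4.12) and TCF7L2 (-1.79), with SFRP1 (-0.92) and CTNNB1 (-0.68) not called. Of the interferon response list 5 of 11 were lower (median -1.23), with IFITM3 and B2M (-1.27) among them and ISG15 (-1.23) not called. Ribosomal protein genes had a median of -0.63, and 6 of 28 were lower in every set, among them RPS19 (-1.16) and RPS2 (-0.76), while RPL10 (-0.33) and RPLP1 (-0.45) were not called. Lysosome and autophagy genes had a median of -0.62 with 4 of 19 lower; NPC2, a cholesterol carrier of the lysosome, was at -2.24, and PSAP (-0.62), MAP1LC3B (0.60) and GABARAPL2 (0.27) were not called. The lysosome median ran from -0.82 to -0.33 over the alternatives. DNA replication genes had a median of -0.25 with 2 of 13 lower, and mitosis genes of -0.73 with none of 8 called. Cells with cycling markers raised had been named as a class of their own. These medians therefore cannot show how neuron-like cells differ from dividing progenitors. Over the alternatives the replication median ran from -0.73 to -0.052 and the mitosis median from -0.75 to -0.29.

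None of 25 oxidative phosphorylation genes and none of 13 mitochondrially encoded genes passed 1.5-fold between neuron-like and neural progenitor-like cells in every set, with medians of 0.11 and -0.071 (-0.076 to 0.19 and -0.26 to -0.024 over the alternatives). Folds of the most abundant members ran from -0.11 (COX7C) to 0.26 (NDUFA4) in the nuclear list, with COX4I1 at 0.086 and COX6A1 at 0.24, and were -0.16 for MT-CO1, -0.21 for MT-CO2, -0.060 for MT-CO3 and -0.29 for MT-ATP6. Glycolysis and hypoxia genes had a median of 0.24 (2 higher and 2 lower of 18), with TPI1 at 0.088, GAPDH at 0.023, ENO1 at -0.46 and LDHB at -0.15; the median ran from 0.0021 to 0.31 over the alternatives. Heat shock genes had a median of 0.13 with 1 of 11 lower, and HSP90AA1 was at 0.69, HSPA8 at 0.43, HSP90AB1 at 0.13 and HSPE1 at -0.35. None of 10 oxidative stress genes passed (median 0.073), with FTH1 at 0.43, GPX4 at 0.15, FTL at -0.11 and PRDX1 at -0.42. With totals taken without mitochondrial, ribosomal protein and MALAT1 transcripts the medians of oxidative phosphorylation, heat shock and oxidative stress genes were -0.076, -0.066 and -0.20, so the direction of these 3 lists rests on the scaling. The oxidative stress median was -0.11 without set 4, and the heat shock median was -0.14 without sets 1 to 4. Of 17 unfolded protein response genes 4 were higher and 4 lower (median -0.0038), the latter including HSPA5 (-0.93), HSP90B1 (-0.89) and CALR (-0.84), with ATF4 (0.21) not called, and the median ran from -0.34 to 0.058 over the alternatives. Cholesterol synthesis genes had a median of -0.34 with 1 of 15 lower, HMGCS1 standing at -0.93 and FDPS at -0.65, and ran from -0.52 to -0.21 over the alternatives. The median was -0.68 for p53 and apoptosis genes with 5 of 15 lower, including CDKN1A (-1.59), MDM2 (-1.02) and BAX (-1.38), and TP53I3 (-0.33) not called; the list median ran from -1.02 to -0.38 over the alternatives. Immediate early genes had a median of -0.62 with 3 of 14 lower and 1 higher; FOS was at -2.80, JUN at -0.89, JUND at 0.48 and PDE4B at 0.22, and the median ran from -0.81 to -0.40 over the alternatives. Only 3 metallothionein and 2 inflammation genes were measured, with medians of -1.19 and 0.62; MT2A (-2.08) and MT3 (-1.19) were lower, MT1X (0.83) was not called, and NFKBIA and IER3 stood at 0.76 and 0.48. Without sets 1 to 4 both medians turned, to 0.080 and -0.55.

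In the list of amyloid precursor processing and Alzheimer risk genes, 1 of 22 was higher and 3 were lower in neuron-like cells in every set, with a median of -0.27 (-0.43 to -0.10 over the alternatives). MAPT was the higher one, at a median of 234 CPM in neuron-like and 8.71 CPM in progenitor-like cells (log2 fold 3.25). It is also a mature neuron marker used for naming. APOE, which encodes a lipid carrier, was lower at 9.17 against 61.5 CPM (-2.81), CLU, which encodes clusterin, at 58.5 against 372 CPM (-2.64), and the protease gene BACE2 at 1.14 against 11.4 CPM (-2.20). APP stood at 342 and 262 CPM, and its fold of 0.39 ranged from -0.20 to 0.60 over sets; APLP1 and APLP2 had folds of 0.85 and 0.30.

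Cells of clusters 9 and 10 were pooled and compared with neural progenitor-like cells; they came mostly from cluster 10 in sets 1 and 2 and from cluster 9 in sets 3 to 6. Of 10432 genes 530 were at least 1.5-fold higher and 374 lower in clusters 9 and 10 in each of the 6 sets, 300 and 204 with a pseudocount of 10 CPM, and 1104 and 730 without sets 1 to 4, which leaves fewer sets to pass in. With cluster 10 alone, in the 3 sets with at least 50 of its cells, 958 were higher and 889 lower. The leading genes were POU2F2 (5.38, from 1.72 to 5.82), CRABP1 (4.79), THSD7A (4.64), STMN2 (4.45), INSM1 (4.44), TTC9B (4.28), SSTR2 (4.26) and SRRM4 (3.75), and in the other direction IFITM3 (-3.10), CTGF (-2.82), SFRP2 (-2.65), SPARC (-2.55), TTYH1 (-2.48), CD99 (-2.39), NTRK2 (-2.28) and FBXO32 (-2.26). With cluster 10 alone POU2F2 was at 1.88, THSD7A at 2.92, STMN2 at 2.05 and TTC9B at 1.29, while CRABP1 was at 4.88 and INSM1 at 4.15. Of 11 Notch genes 6 were lower and 2 higher (median -1.20), HES5 at -1.98, HES4 at -1.10 and DLL3 at 2.34, with JAG1 (-1.20) not called. HES5 and HES4 are also neural progenitor markers used for naming, and INSM1 and DLL3 are intermediate progenitor markers. Their folds and the Notch median are thus no independent test. Presynapse genes had a median of 1.73 (0.78 to 1.91 over the alternatives) with 9 of 19 higher, and axon guidance genes of 1.00 with 10 of 26 higher and 1 lower. Matrix genes had a median of -1.16 with 6 of 13 lower, and ran from -1.33 to -0.68 over the alternatives. APOE (-2.33), CLU (-1.48), BACE2 (-1.49) and SORL1 (-1.19) were lower and MAPT (1.26) was higher. With the clustering made without list and marker genes 314 genes were higher. The Notch median ran from -1.28 to -0.26 over the alternatives, some of which regroup the cells.

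Of 10433 genes 729 were higher and 139 lower in cycling-like than in neural progenitor-like cells in each of the 6 sets. The lower genes numbered 249 at a resolution of 1.0, 437 with 50 components, 281 without marked doublets, 239 with totals without mitochondrial, ribosomal protein and MALAT1 transcripts, and 59 with a pseudocount of 10 CPM. Without sets 1 to 4, which leaves fewer sets to pass in, 1219 were higher and 827 lower. The cluster was named for markers such as TYMS, PCNA and CENPF, which are also members of the replication and mitosis lists. All 20 replication genes were higher, with a median of 3.54, and TYMS stood at 407 against 34.9 CPM, MCM7 at 2.93 on the log2 scale and PCNA at 284 against 37.8 CPM. All 22 mitosis genes were higher with a median of 4.74, CENPF standing at 700.5 against 18.3 CPM and HMGB2 at 509 against 19.7 CPM. Cycling-like cells numbered 90 in set 1. The leading genes were MKI67 (6.38, from 5.28 to 6.69), RRM2 (6.09), TOP2A (6.07), UBE2C (6.03), ASPM (5.89), MCM10 (5.84), NUSAP1 (5.76) and DLGAP5 (5.75). Lower in cycling-like cells were IGFBP5 (-2.27), JAG1 (-2.06), PNRC1 (-1.96), PCSK1N (-1.32), NEAT1 (-1.32), FBXO32 (-1.29), MXD4 (-1.23) and IGBP1 (-1.12). Of 18 glycolysis and hypoxia genes 3 were higher (median 0.34, percentile 99.5); TPI1 (0.83), ENO1 (0.71), GAPDH (0.61) and LDHB (0.15), the most abundant, were not among them. APOE (-1.28), CLU (-0.99) and LRP1 (-1.04) were lower, and the Notch list had a median of -0.095 with 1 gene higher and 1 lower of 10, and of 0.11 with the clustering made without list genes. The median was -0.65 for ion channel genes (1 of 8 higher, none lower), -0.42 for lysosome genes (1 of 19 lower) and -0.26 for ribosomal protein genes (none of 28 called), at percentiles 0.06, 0.03 and 0.09. Without sets 1 to 4 the ion channel median was 0.020.

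**Figure D3:**
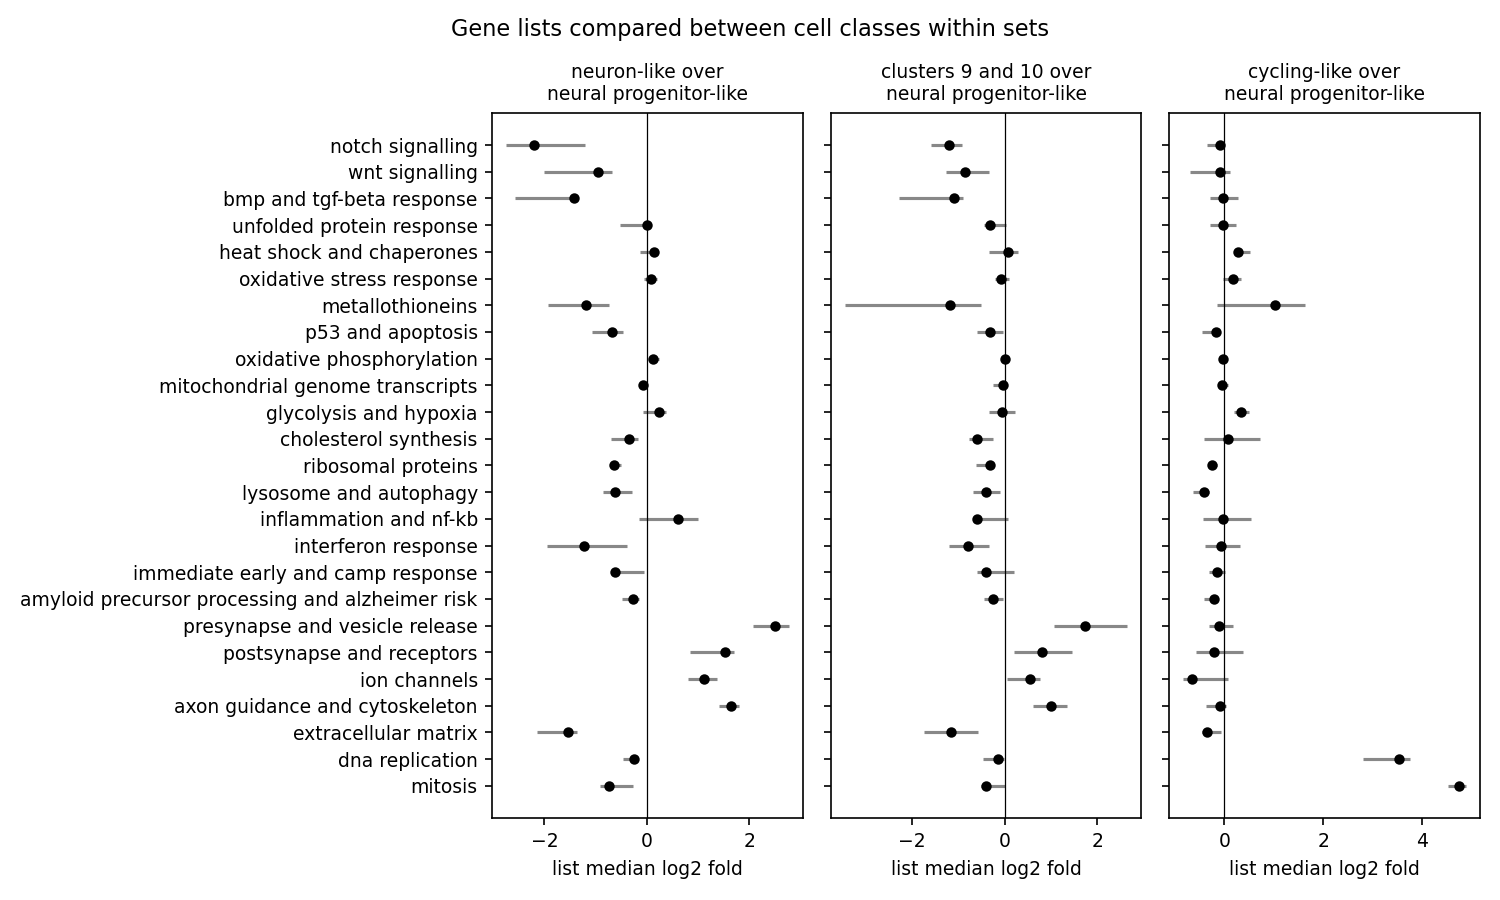
Points give the median log2 fold of each gene list (horizontal axis) for the lists named on the vertical axis, with 1 panel for each pair of classes, and lines span the lowest and highest of the 6 sets. The presynapse list lies at 2.51 for neuron-like over neural progenitor-like cells and the mitosis list at 4.74 for cycling-like over neural progenitor-like cells.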

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

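The alternatives with a resolution of 1.0, with 50 components and with at least 1000 genes per cell (40637 cells, 3230 of them in set 4) were fixed before the data were examined, and the others were chosen after. The cause of each change was not tested. Under alternatives that regroup the cells, values beside those of clusters 9 and 10 are of the clusters then named for the intermediate progenitor list. At a resolution of 1.0 the cells formed 21 clusters in place of 11, with neural progenitor-like 19.6%, cycling-like 20.9%, neuron-like 37.7% and unnamed 9.51% of cells, and 595 cells (1.40%) took the name of the stress list. With 50 components the shares were 20.9% (neural progenitor-like), 6.15% (cycling-like), 8.98% (intermediate progenitor-like) and 40.5% (neuron-like). With at least 1000 genes per cell neural progenitor-like cells were 18.7% and unnamed 26.6%. Without list and marker genes in the clustering the shares were 31.2% (neural progenitor-like), 7.51% (intermediate progenitor-like), 40.6% (neuron-like) and 14.4% (unnamed). Without the cells marked as doublets they were 21.1% (neural progenitor-like), 6.05% (cycling-like), 12.3% (intermediate progenitor-like) and 24.1% (unnamed), and without the 5% of cells with most UMIs 21.7% (neural progenitor-like), 5.64% (cycling-like) and 37.9% (neuron-like). With cluster 9 left unnamed, cluster 10 alone was 5.52% and unnamed cells 29.1%. Leaving out sets changes the cells that are counted, and so the shares by construction. Without set 4 they were 18.7% (neural progenitor-like), 6.22% (cycling-like), 11.5% (clusters 9 and 10), 37.4% (neuron-like) and 26.1% (unnamed). Without sets 1 to 4 they were 1.496%, 10.7%, 10.6%, 14.1% and 63.1% in the same order.

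For neuron-like cells the 1214 higher and 753 lower genes became 1911 higher with 50 components, and 770 higher and 493 lower with a pseudocount of 10 CPM. For clusters 9 and 10 the 530 higher and 374 lower became 314 higher without list and marker genes, 300 and 204 with the larger pseudocount, 958 and 889 with cluster 9 left unnamed, and 1104 and 730 without sets 1 to 4. For cycling-like cells the 139 lower genes became 249 at a resolution of 1.0, 437 with 50 components, 281 without marked doublets, 239 with totals without mitochondrial, ribosomal protein and MALAT1 transcripts, 59 with the larger pseudocount and 827 without sets 1 to 4, where 1219 were higher. Without sets 1 to 4 there are fewer sets to pass in, and with cluster 9 left unnamed both the sets and the cells compared change.

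Of 775 list medians under alternatives, 68 changed sign, 10 of them from a median with 1 sign in every set. These 10 aside, 617 moved by less than their SD over sets and 148 by more. Of 496 folds of the leading genes of each comparison, which were chosen as the largest, 398 moved by less and 98 by more. The other named genes were not run under the alternatives. In clusters 9 and 10 the ion channel median, 0.54, was -0.17 at a resolution of 1.0 and with 50 components, -0.0045 with at least 1000 genes, -0.20 without list genes and 0.096 with cluster 10 alone, and the DNA replication median, -0.15, was 0.0038 with 50 components and 0.0019 with at least 1000 genes. The Notch median of cycling-like cells, -0.095, was 0.11 without list genes. Without sets 1 to 4 metallothioneins were 0.080 in neuron-like cells and 1.56 in clusters 9 and 10 (there almost wholly cluster 9), against -1.19 and -1.18. Totals without mitochondrial, ribosomal protein and MALAT1 transcripts moved the median of all genes from 0.15 to -0.020 in neuron-like, from 0.12 to 0.0053 in clusters 9 and 10 and from -0.026 to -0.12 in cycling-like cells, and oxidative phosphorylation in neuron-like cells from 0.11 to -0.076. Without list genes the median of all genes beside that 0.12 was -0.0096. The alternatives for tests of treatment and day were not run, and no paired analysis was possible, because no cell could be tied to a library.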

Other observations

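The region and serotonergic genes below were chosen after the data were seen. Of 9 genes read for the serotonergic lineage 6 (FEV, GATA2, GATA3, LMX1B, TPH2 and GCH1) had their 2 highest levels in clusters 7 and 9; FEV and GATA3 are also leading genes of these clusters. FEV, a transcription factor of serotonergic neurons, stood at 228 CPM in cluster 7 and 266 CPM in cluster 9, and GATA3 at 102 and 160 CPM. A UMI of FEV was seen in 20.5% and 32.5% of their cells and of GATA3 in 18.1% and 24.2%, a minority in each case. LMX1B was at 24.8 and 45.9 CPM and TPH2, which encodes the rate-limiting enzyme of serotonin synthesis in neurons, at 8.79 and 15.8 CPM, with a UMI of TPH2 in 3.32% and 4.29% of cells. In cluster 3, which is also neuron-like, FEV was at 8.76 CPM and TPH2 at 0.381 CPM, but GATA2 was at 37.1 CPM, against 49.1 CPM in cluster 7. DDC was at 14.7 CPM in cluster 7, 24.5 CPM in cluster 9 and 16.6 CPM in cluster 11. The transporter genes SLC6A4 and SLC18A2 were low, at 0.542 and 1.05 CPM in cluster 7 and at 0.843 and 0.0702 CPM in cluster 9.

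Of the hindbrain genes read, HOXB2 ranged from 41.7 to 94.7 CPM over the 7 sets, HOXB3 from 5.08 to 38.2 CPM and HOXB4 from 0.522 to 19.0 CPM, while HOXA2 (0.261 to 1.87 CPM) and HOXA5 (at most 0.599 CPM) were low. Of the genes of the boundary of midbrain and hindbrain, GBX2 ranged from 20.0 to 86.0 CPM, EN1 from 4.80 to 26.7 CPM and EN2 from 3.98 to 35.9 CPM, and PAX2 reached 9.54 CPM with a median of 0.547 CPM over sets. The forebrain genes EMX2, SIX3, LHX2 and OTX1 reached at most 1.41, 0.146, 1.52 and 0.887 CPM in any set.

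Expression profiles of the sets, as correlations over 10678 genes within the pool (genes are not independent replicates), were closest between sets 1 and 2 (r = 0.997), sets 3 and 4 (0.996) and sets 5 and 6 (0.995). Set 7 correlated at 0.684 to 0.861 with the others. These values were not used to tie a set to a library.

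All 4 tests reported here were chosen after the patterns they address had been seen. In set 4 100% of counts were even. Had every count been written at 2 times its value, 4s as a percentage of 2s would resemble 2s as a percentage of 1s elsewhere, and had odd counts been removed it would resemble 4s as a percentage of 2s elsewhere. Among genes seen in 0.2% to 10% of cells it was 3.98%, against 4.62% to 5.49% for the former and 1.09% to 2.58% for the latter in sets 5 to 7. Doubled counts may thus be the source; why this set differs was not tested. In sets 1 to 3 counts of 2 were 37.0%, 22.9% and 17.4% of the number of counts of 1 among such genes, and 4.98%, 5.49% and 4.62% in sets 5 to 7. Expression that differs between cells is argued against, because any mixture of Poisson counts gives a quotient of 1 or more for the ratio of 3s to 2s times 3 over the ratio of 2s to 1s times 2, and the highest quotient of the 3 sets was 0.872. The ratio of 2s to 1s differed by at most 1.04-fold between neuron-like and other cells of a set. It was not split by class in sets 5 to 7, which lack the excess, so this likeness cannot decide the source. Molecules counted more than once remain possible. No explanation by day or treatment was tested, since no set could be tied to a group.

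TUBB3, a marker of young neurons, stood at 1.81 to 3.87 CPM in the 7 sets, although DCX reached 569 CPM. The median over sets of the lower log2 fold of TUBB3 and its annotated neighbour MC1R (neuron-like over neural progenitor-like cells) was 0.55, and both genes had few UMIs. MC1R stood at 0.661 to 3.38 CPM in the 7 sets. This argues against TUBB3 reads counted as MC1R in numbers near those of DCX in sets 1 to 6. Reads lost without a count for either gene remain possible but unproven. The fold cannot decide this, as such a loss need not raise MC1R.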
